A study of Macaca mulatta with 7 samples.

How the data were processed

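Total RNA from the sperm of 7 rhesus macaques was analysed from the deposited processed files, 1 library for each of 4 Control and 3 Maltreated animals, grouped by the labels. Per the submitters' processing notes, STAR, featureCounts and bedtools were used, with no version, role or order given. The genome build is not given in the sources used here, so coordinates are those of the deposited files, with chromosomes 1 to 19 (2a and 2b in place of 2) and X.

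For every library a forward and a reverse file hold, per the file layout as deposited, the count of reads that overlap each annotated exon, with no normalisation. The same files hold the fraction of each exon covered by reads, as deposited, computed by the authors from covered bases over exon length. A table of the whole series holds, per the file headers, the read count and the covered fraction of each gene as deposited, split into reads on the strand of the gene (sense) and on the opposite strand (antisense). The counts of this table were checked against the exon files and equalled the sums over exon entries for sense and antisense reads in all 7 libraries. A read that overlaps several exons is thus counted on each of them. Of the exon entries, 43085 of 233690 (18.4%) repeat an exon of the same gene, in 2174 genes; the deposited sums were used as they are. The files name 18284 genes by symbol only. Of these, 16123 are current symbols in the annotation supplied with the data, 422 match a synonym and 1739 match none. RTN3 and ZC3HAV1 are listed on both strands and were left out, which leaves 18282 genes. No mitochondrial gene and no gene of structural noncoding RNA is in the files.

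The comparison, tests, gene lists, named-gene rule and most alternatives were chosen before the data were examined. That design did not foresee a table split into sense and antisense reads. The sense counts were taken as the counts of a gene, and antisense counts were added as a further comparison.

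Genes were tested with edgeR 4.0.16 in R 4.3.3 with TMM factors, filterByExpr with its minimum count of 10 and minimum total of 15, and the quasi-likelihood F test on the group. The p values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. The fit has 5 residual degrees of freedom. Gene lists with at least 5 tested members were compared with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over 14 lists. Camera with an estimated correlation and fry were run beside it, and members were also adjusted over the list alone. The 17 lists cover sperm and spermatid structure, axoneme and motility, earlier germ cells, testis somatic cells, leukocytes, epithelium and accessory glands, erythroid cells, mitochondrially encoded genes, cytosolic ribosomal proteins, nuclear oxidative phosphorylation, glucocorticoid and HPA axis, heat shock and oxidative stress, chromatin and DNA methylation, small RNA pathway, neuronal and synaptic genes, imprinted genes and structural noncoding RNA. Measures of whole libraries were compared with two-sided exact permutation tests over all 35 splits, adjusted within the family of composition, breadth or list levels.

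The genes named are, in each direction, the 10 with the largest change among those passing the test without overlap of the groups, filled up with the smallest unadjusted p. Since 0 passed, all 20 were chosen by unadjusted p. Of each list the 3 tested members with the smallest unadjusted p are named, and the 10 genes with the highest mean CPM, 74 genes in all. Genes outside this rule were chosen after their values were seen. They are the leukocyte genes CD74, ITGAM, LYZ, CSF3R and TYROBP, CD63 and the antisense genes. So were the macrophage genes CTSB, PSAP, CTSD, FTL, B2M, CSF1R, TREM2 and SPI1, and the lymphocyte genes LCK, IL7R, PAX5, KLRD1 and CD22. CPM of named genes are scaled with TMM factors over the tested genes. CPM of list levels and of single leukocyte, macrophage and lymphocyte genes in 1 library are scaled to all sense counts. A fold against a group without counts uses a floor of 3 counts over the group, and ratios with 1 to 3 counts in a group carry an exact 95% binomial interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Depth ran from 5316383 to 30715268 sense counts per library.

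Alternatives covered DESeq2 1.42.0 size factors, total counts and upper-quartile scaling in edgeR, the DESeq2 Wald test, limma-voom with sample quality weights, no filter and a filter on a mean count of 10. They also covered a block on the replicate number, age as a covariate, forward or reverse files alone, and leaving out each library in turn. Alternatives chosen after seeing the data were unique exons only, sense plus antisense counts, leaving out Control 4 and Maltreated 3 together, and exon counts above the lower neighbour. In the last of these each exon was reduced to its count above the lower of the counts of its neighbours. All alternatives of the antisense comparison were chosen after seeing the data as well, and so was camera with an estimated correlation without each library, with the block or with exon counts above the lower neighbour.

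The gene tests were run on simulated counts, with 50 genes changed at each size. The counts were drawn with the means, library sizes and fitted dispersions of the real genes. With the fitted dispersion the sense comparison over 10719 genes found 6 of 50 genes changed 4-fold, 22 at 16-fold and 34 at 64-fold, and called 2 of 10519 unchanged genes. The antisense comparison over 4382 genes found 0, 2 and 16 of 50 at the same sizes. For the list test the real log2 CPM of each gene were shuffled over the libraries, separately for each gene. Of 100 random lists, 3 then had a camera p under 0.05. The shuffling removes the correlation between genes, so this does not show how camera behaves on lists of correlated genes. Library tests, exon measures and figures were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.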

Results

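Total RNA was sequenced from the sperm cells of 7 rhesus macaques (Macaca mulatta), 4 of a Control group and 3 of a group that the submitters call Maltreated. The series title places the comparison in the question of what early life stress leaves behind in the RNA of the primate germline. The sperm were purified on a PureSperm 40/80 density gradient, which separates sperm from round cells and debris, and the RNA was extracted with TRIzol. The animals were 5.67 to 5.92 years old. Reads on the annotated strand of a gene (sense) came to 9847743, 5528056, 6002772 and 5316383 in Control 1 to 4. In Maltreated 1 to 3 they came to 30715268, 6160996 and 10690315. Reads on the opposite strand (antisense) made up 6.85, 10.4, 8.86 and 12.1% of the counts in Control 1 to 4 and 6.15, 9.69 and 8.45% in Maltreated 1 to 3. Between 11542 and 16983 genes had a sense count, the lower number in Maltreated 2 and the higher in Maltreated 1.

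The most abundant transcript over the 7 libraries was that of PRM2, a protamine that packs sperm DNA. It stood at 36541 ± 5217 CPM (the count scaled to the total of the library; SD, n = 4) in Control and 43919 ± 26261 (SD, n = 3) in Maltreated sperm. PRM1, the other protamine among the 10 most abundant genes, stood at 6581 ± 1076 (SD, n = 4) and 7135 ± 2044 (SD, n = 3). MUC16, a membrane mucin, had 36200 ± 15491 CPM (SD, n = 4) against 31302 ± 1834 (SD, n = 3). RIMS1, a regulator of vesicle release, had 22979 ± 5532 (SD, n = 4) against 24892 ± 6088 (SD, n = 3). UBXN7, RPL38, CEP112 and GON4L had group means between 6857 and 14429 CPM. ANKRD36 and ANKRD36B completed the 10, but their annotated loci overlap on the same strand of chromosome 2a, so reads can be shared between them and their separate levels are uncertain. Over these 10 genes the log2 fold change of Maltreated over Control ran from -0.30 ± 0.23 (SE) in GON4L to 0.27 ± 0.33 in PRM2, and none passed the test. Without Maltreated 1, the library with 74203 CPM of PRM2, the log2 fold change of PRM2 was -0.35.

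**Figure D1:**
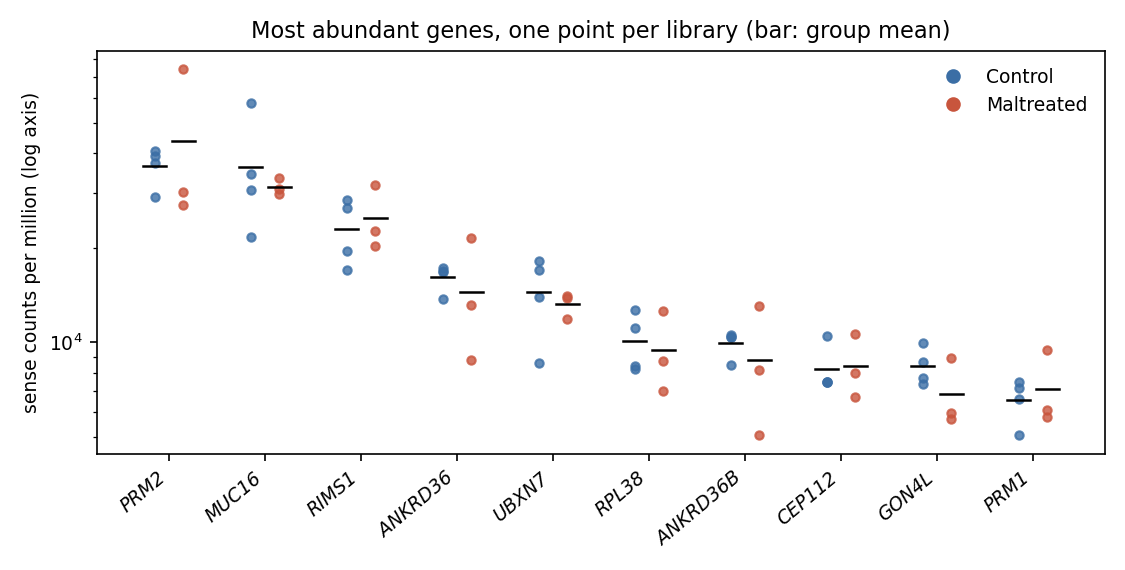
CPM of sense reads (log axis) for the 10 genes with the highest mean over the 7 libraries, in Control (blue) and Maltreated (red) sperm. Each point is 1 library and each bar a group mean; for PRM2 the Control libraries lie between 29016 and 40657 CPM and the Maltreated libraries between 27429 and 74203.

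The main comparison asked which genes differ in sperm RNA between Maltreated and Control animals. PAQR6, a membrane progestin receptor, had 0.214 ± 0.427 CPM (SD, n = 4) in Control and 130 ± 217 (SD, n = 3) in Maltreated sperm, with 381 CPM in Maltreated 2 alone. PDCD1LG2, a ligand of the PD-1 immune receptor, had no count in any Control library and 434 counts in the Maltreated libraries. It was thus at least 81.2-fold higher against a floor of 3 counts over the Control group. This bound was 42.8 without Maltreated 1, which held 353 of the counts, and 51.2 to 90.3 without each other library. IL17RC, a subunit of the interleukin-17 receptor, had 1 Control count and 161 Maltreated counts, a ratio of 90.4 with a counting interval of 15.99 to 3591 (95%, exact). The ratio was 55.7 without Maltreated 3 and 166 without Maltreated 1, and without Control 2, which held the only Control count, the bound was at least 23.9-fold. With antisense counts added the log2 fold change of PDCD1LG2 was 2.84 and that of IL17RC 3.31. MYO18A, an unconventional myosin, stood at 9.98 ± 3.17 CPM (SD, n = 4) against 42.1 ± 19.2 (SD, n = 3). BCOR, a transcriptional corepressor, stood at 3.38 ± 3.02 (SD, n = 4) against 32.6 ± 30.3 (SD, n = 3). EIF4A1, a helicase of translation initiation, stood at 8.65 ± 2.49 (SD, n = 4) against 42.3 ± 32.4 (SD, n = 3). HIF1A, a transcription factor of the hypoxia response, stood at 7.82 ± 4.88 (SD, n = 4) against 45.7 ± 38.4 (SD, n = 3). Each of these 7 genes was higher in 3 of 3 Maltreated libraries than in every Control library, but none passed the test. The log2 fold change of BCOR, 3.25 ± 0.94 (SE), was 2.13 without Maltreated 2 and 4.06 without Control 1.

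In EIF4A1 and HIF1A the highest library was Maltreated 3, with 78.4 and 88.6 CPM, and this library also had the most RNA of leukocyte genes. Without it their log2 fold changes were 1.49 in place of 2.29 and 1.62 in place of 2.54. The other named genes of this direction were CSRP1, a LIM domain protein gene, with a log2 fold change of 4.67 ± 1.398 (SE), the synaptic scaffold gene DLG4 with 3.82 ± 1.18, and the cartilage glycoprotein gene LECT1 with 5.47 ± 1.72. DLG4 reached 197 CPM in Maltreated 2 but 2.86 in Maltreated 3, which lies within the Control libraries. The log2 fold change of DLG4 was 0.84 without Maltreated 2, 1.00 by limma-voom with sample weights, and 0.32 with each exon reduced to its count above the lower of its neighbours. LECT1 reached 95.3 CPM in Maltreated 2 against 5.03 and 8.24 in the other Maltreated libraries. Without Maltreated 2 the log2 fold change of LECT1 was 3.04 and that of CSRP1 3.805. For LECT1 it was 11.6 without Control 1, which held all 28 of its Control counts. In some of these genes many counts lay on exons whose count equalled that of both neighbours. The share of counts in such runs was 83.0% in PAQR6, 63.7% in DLG4, 47.5% in LECT1, 46.3% in IL17RC and 18.8% in MYO18A, and at most 2.37% in the other 5. With each exon reduced to its count above the lower neighbour the log2 fold change of MYO18A was 1.05 in place of 2.07, and PAQR6, LECT1 and IL17RC had too few counts left to be tested.

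Among the genes with less RNA in Maltreated sperm, CA11, NTN5 and DBP lie near each other on the minus strand of chromosome 19, between positions 43521644 and 43564460. CA11, which encodes a carbonic anhydrase-related protein, stood at 63.8 ± 95.7 CPM (SD, n = 4) in Control and 1.22 ± 1.28 (SD, n = 3) in Maltreated sperm. NTN5, a netrin gene, stood at 53.1 ± 72.1 (SD, n = 4) against 3.52 ± 1.94 (SD, n = 3). DBP, a transcription factor of the circadian clock, stood at 36.2 ± 37.9 (SD, n = 4) against 4.34 ± 1.35 (SD, n = 3). Control 4, the Control library with the most RNA of leukocyte genes, had the highest level of all 3 genes, with 206 CPM of CA11, 160 of NTN5 and 91.8 of DBP, and nearly every exon of the 3 genes carried a count of 123 in it. The same exons carried mostly 20 counts in Control 2, 9 in Control 1 and 4 in Control 3. Runs of identical counts held 79.7% of the counts of CA11, 62.4% of NTN5 and 15.7% of DBP. With each exon reduced to its count above the lower neighbour the log2 fold change of DBP was -0.82 in place of -3.07 and that of NTN5 -1.33 in place of -3.89, and CA11 had too few counts left to be tested. Without Control 4 the log2 fold change of DBP was -2.04 and that of NTN5 -2.30.

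**Figure D2:**
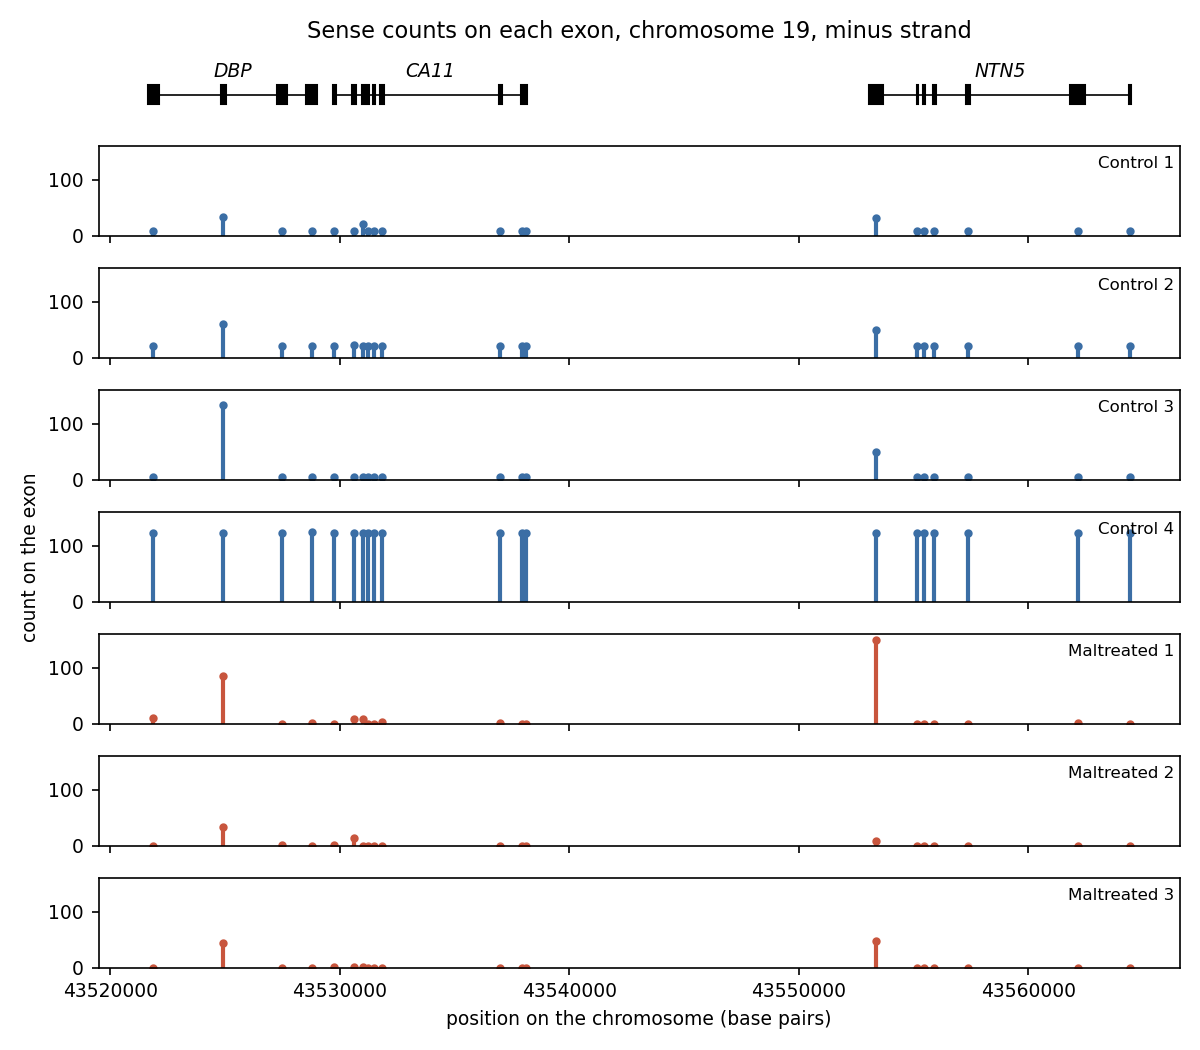
Sense counts on each exon (vertical axis, counts) along chromosome 19, minus strand (horizontal axis, base pairs), over DBP, CA11 and NTN5, whose exons are drawn as boxes at the top; each panel is 1 library. In Control 4 most exons carry 123 counts, and in Control 2 most carry 20.

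PPP2R2C, a regulatory subunit of a protein phosphatase, stood at 349 ± 405 CPM (SD, n = 4) in Control and 25.5 ± 0.761 (SD, n = 3) in Maltreated sperm. Control 2 held 918 CPM of it and Control 1 only 21.02, below the Maltreated libraries. CHIA, an acidic chitinase gene, stood at 46.8 ± 67.5 (SD, n = 4) against 1.205 ± 1.404 (SD, n = 3), with 148 CPM in Control 4, and a log2 fold change of -1.204 with antisense counts added in place of -5.17. ZNF140, a zinc finger gene, stood at 164 ± 109 (SD, n = 4) against 50.3 ± 13.0 (SD, n = 3). USHBP1 had 82 counts in the Control libraries and none in the Maltreated libraries, at least 48.7-fold lower against a floor of 3 counts over the Maltreated group, and 74.4% of its counts lay in runs of identical counts. This bound was 28.2 without Control 1, which held 52 of the counts, 17.3 without Maltreated 1, and 37.8 to 62.1 without each other library. With antisense counts added the log2 fold change of USHBP1 was -0.79. TTC33 (log2 fold change -3.21 ± 0.97, SE) was highest in Control 1 and Control 3, with 122 and 111 CPM. PTMS, the parathymosin gene, had a log2 fold change of -1.74 ± 0.53 (SE). The potassium channel gene KCNH3 had one of -4.61 ± 1.48 (SE), with 59.9% of its counts in runs of identical counts. Control 1 held 122 CPM of KCNH3 and Control 4 only 0.186, below the Maltreated libraries at 1.30 to 4.01, and without Control 1 its log2 fold change was -3.78.

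In the edgeR test, 0 of 10719 genes passed an adjusted p of 0.05 in either direction, and the smallest adjusted p was 0.999. At an unadjusted p under 0.05 there were 191 genes (313 without Control 4), where a nominal 5% is 536. The other splits of the 7 libraries into 4 and 3 gave 218 to 755 such genes, so the real split had the fewest. In 385 genes (3.59%) the 2 groups did not overlap, where chance gives 5.71%. The biological coefficient of variation was 0.858, so the spread between animals of 1 group was nearly as large as the mean of a gene. The unadjusted p of the 20 genes above ran from 0.000796 for PAQR6 to 0.0105 for KCNH3. The DESeq2 Wald test on the same counts called 3 genes, all lower in Maltreated sperm. By DESeq2 these were CA11 (log2 fold change -5.80, adjusted p = 0.000867), PPP2R2C (-3.79, adjusted p = 0.0137) and CHIA (-5.31, adjusted p = 0.0137). Their highest single libraries were Control 4, with the most RNA of leukocyte genes in its group, for CA11 and CHIA and Control 2 for PPP2R2C. In edgeR, leaving out Control 4 took the log2 fold change of CA11 from -5.78 to -3.797 and that of CHIA from -5.17 to -3.40, and leaving out Control 2 took that of PPP2R2C from -3.78 to -2.64.

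Genes of sperm and spermatid structure, which include the protamines, acrosome and sperm tail proteins, summed to 61307 ± 4851 CPM (SD, n = 4) in Control and 69127 ± 30600 (SD, n = 3) in Maltreated sperm. Of 37 tested members 18 were higher and 19 lower in Maltreated sperm. Their median log2 fold change was -0.01 and their mean 0.03, and camera gave an adjusted p of 0.830 in the downward direction. SPATA3 had 191 ± 45.8 CPM (SD, n = 4) against 317 ± 184 (SD, n = 3), and a log2 fold change of 0.13 without Maltreated 1 in place of 0.73. ACRBP, an acrosin-binding protein gene, had 34.97 ± 13.9 (SD, n = 4) against 18.9 ± 2.56 (SD, n = 3). CRISP2, a cysteine-rich secretory protein gene, had 612 ± 621 (SD, n = 4) against 322 ± 95.4 (SD, n = 3). CRISP2 reached 1539 CPM in Control 4, and without that library its log2 fold change was 0.07 in place of -0.93.

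Genes of the axoneme and of motility, the moving core of the sperm tail, had 25 of 35 tested members lower and 10 higher, with a median log2 fold change of -0.18 (camera adjusted p = 0.377). The tektin gene TEKT1 stood at 4.31 ± 1.44 CPM (SD, n = 4) against 12.9 ± 2.88 (SD, n = 3), above every Control library in 3 of 3 Maltreated libraries. DNAH2, a dynein heavy chain gene, stood at 235 ± 144 (SD, n = 4) against 126 ± 12.5 (SD, n = 3), and its log2 fold change was -0.29 in place of -0.90 with each exon reduced to its count above the lower neighbour. CATSPER4, a sperm calcium channel gene, stood at 42.1 ± 65.3 (SD, n = 4) against 8.95 ± 2.41 (SD, n = 3), with 139 CPM in Control 3, and its log2 fold change was -0.12 without that library in place of -2.23. Without Maltreated 2 the axoneme list passed camera downwards (adjusted p = 0.0192, and 0.564 with an estimated correlation), and without Maltreated 3 its adjusted p was 0.931. Genes of earlier germ cells, mostly meiotic, had 16 of 24 tested members lower (median -0.35, camera adjusted p = 0.417). They summed to 1280 ± 80.3 CPM (SD, n = 4) in Control and 1300 ± 195 (SD, n = 3) in Maltreated sperm. Their members with the smallest p were MEIOB with a log2 fold change of 0.69 ± 0.40 (SE), MLH3 with -0.47 ± 0.32 and SYCP3 with -1.75 ± 1.32. SYCP3 had 26.5 CPM in Control 4, and without that library its log2 fold change was 0.19.

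Leukocyte genes set 2 libraries apart from the other 5, 1 in each group. Their summed level was 1128 CPM in Maltreated 3 and 757 in Control 4, and between 13.4 and 73.7 in the other libraries. Whether leukocyte RNA is behind the high levels of other genes in these 2 libraries was not tested. In Maltreated 3 the genes CD68 (lysosomes of macrophages), CD74 (antigen presentation), ITGAM (a myeloid integrin), LYZ (lysozyme) and PTPRC (the common leukocyte antigen) stood at 390, 265, 130, 80.7 and 72.6 CPM. In Control 4 the levels were 502 CPM for CD74, 64.1 for the complement gene C1QB, 30.7 for CSF3R and 29.3 for TYROBP. Of 12 tested members 8 were higher in Maltreated sperm (median log2 fold change 1.22, camera adjusted p = 0.417). PTPRC had a log2 fold change of 3.38 ± 1.45 (SE), CD68 of 4.08 ± 1.95 and C1QB of -3.70 ± 1.82. Without Maltreated 3 the log2 fold changes of PTPRC and CD68 were -0.81 and -2.16, and without Control 4 that of C1QB was 0.11. The list passed camera upwards without Control 4 (adjusted p = 0.0395) and without Maltreated 1 (adjusted p = 0.00615), and its adjusted p without Maltreated 3 was 0.931. Neither call held with an estimated correlation, where the adjusted p was 0.930 without Control 4 and 0.714 without Maltreated 1.

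**Figure D3:**
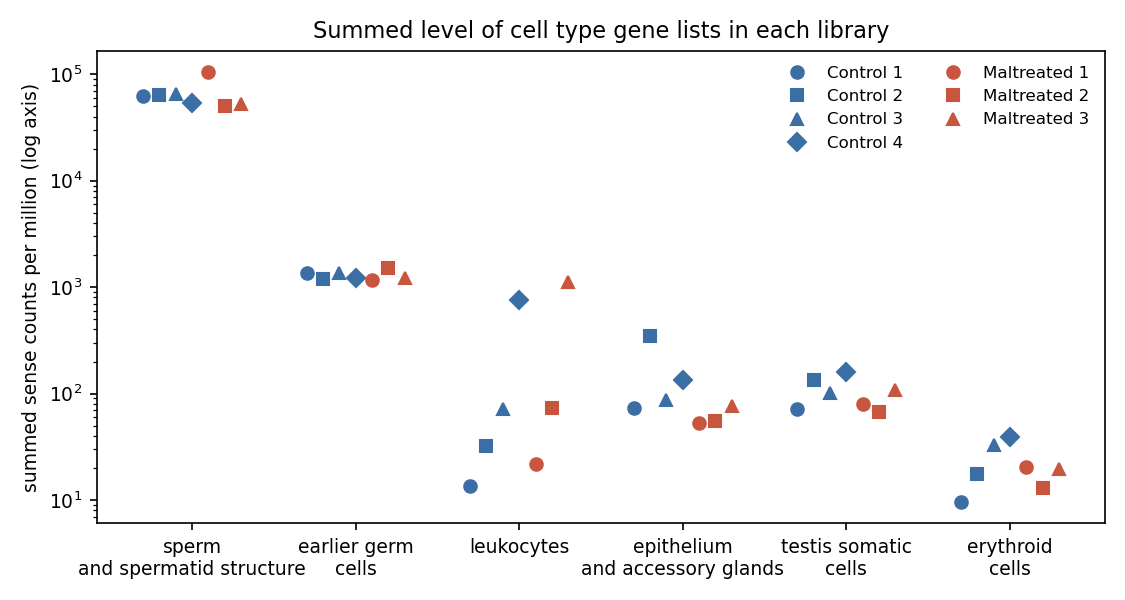
Summed CPM (log axis) of 6 cell type gene lists in each of the 7 libraries; blue symbols are Control libraries and red symbols Maltreated libraries. The leukocyte list stands at 757 CPM in Control 4 and 1128 in Maltreated 3, and at 13.4 to 73.7 in the other 5 libraries.

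Genes of epithelium and accessory glands had 7 of 8 tested members lower in Maltreated sperm, with a median log2 fold change of -1.32 (camera adjusted p = 0.23, and adjusted p = 0.885 with an estimated correlation). MSMB, a prostate secretory protein gene, had a log2 fold change of -3.40 ± 1.56 (SE), and TGM4, a prostate transglutaminase gene, one of -2.95 ± 1.52. Without Control 2 the log2 fold change of TGM4 was -0.010 and that of MSMB -2.79, and without Maltreated 1 that of MSMB was -4.71. KRT8, a keratin gene, had one of -1.77 ± 1.61 (SE), and of 0.31 by limma-voom with sample weights. Control 2 carried 349 CPM of this list, most of it TGM4 at 247 CPM, and the other libraries 53.2 to 133. Genes of testis somatic cells had 6 of 9 tested members lower (median -0.32, camera adjusted p = 0.674). Among them were the collagen genes COL1A1 with -2.12 ± 0.99 (SE) and COL1A2 with -1.33 ± 1.23, while the smooth muscle myosin gene MYH11 had 1.54 ± 0.91. With each exon reduced to its count above the lower neighbour that of MYH11 was 0.14. Erythroid genes had 3 tested members, too few for camera, with HEMGN at -1.38 ± 1.08 (SE), SLC4A1 at 1.76 ± 1.95 and HBB at 0.52 ± 1.03. Their summed level was 24.7 ± 13.4 CPM (SD, n = 4) in Control and 17.6 ± 4.04 (SD, n = 3) in Maltreated sperm.

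Cytosolic ribosomal protein genes had 59 of 84 tested members higher in Maltreated sperm, with a median log2 fold change of 0.32. They summed to 24566 ± 5207 CPM (SD, n = 4) in Control and 27560 ± 5934 (SD, n = 3) in Maltreated sperm. RPS2 stood at 7.88 ± 4.48 CPM (SD, n = 4) against 31.2 ± 9.94 (SD, n = 3) and RPLP2 at 203 ± 60.7 (SD, n = 4) against 307 ± 30.9 (SD, n = 3), each above every Control library in 3 of 3 Maltreated libraries. RPS25 stood at 9.63 ± 4.52 (SD, n = 4) against 27.6 ± 15.9 (SD, n = 3). Camera gave an adjusted p of 0.23 for the list, and an adjusted p of 0.885 with an estimated correlation. The list passed camera upwards without Maltreated 2 (adjusted p = 0.00272) and without Control 2 (adjusted p = 0.049996), and its adjusted p was 0.931 without Maltreated 3, the library with the highest level of leukocyte genes. It also passed upwards when each exon was reduced to its count above the lower of its neighbours (adjusted p = 0.0288). With an estimated correlation the adjusted p was 0.564 without Maltreated 2, 0.993 without Control 2 and 0.754 with these exon counts. Nuclear genes of oxidative phosphorylation had 31 of 67 tested members higher and 36 lower. Their median log2 fold change was -0.04 and their mean 0.10, and camera gave an adjusted p of 0.594 in the upward direction. NDUFA10 (0.65 ± 0.34, SE), NDUFS5 (-1.10 ± 0.66) and UQCRFS1 (-1.18 ± 0.76) had the smallest p among them. UQCRFS1 reached 136 CPM in Control 4, which also had the most RNA of leukocyte genes in its group, and by limma-voom with sample weights its log2 fold change was 0.03.

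Genes of glucocorticoid signalling and of the hypothalamic-pituitary-adrenal (HPA) axis, the hormonal stress response, had 9 of 17 tested members higher and 8 lower (median log2 fold change 0.07, camera adjusted p = 0.674). The glucocorticoid-induced gene TSC22D3 stood at 1.92 ± 1.46 CPM (SD, n = 4) against 5.41 ± 2.92 (SD, n = 3), and the kinase gene SGK1 at 7.54 ± 4.25 (SD, n = 4) against 18.8 ± 22.6 (SD, n = 3). HSP90AB1, a chaperone of the glucocorticoid receptor, stood at 26.6 ± 19.8 (SD, n = 4) against 55.7 ± 69.99 (SD, n = 3). All 3 were highest in Maltreated 3, the library with the most RNA of leukocyte genes, at 8.77, 44.9 and 136 CPM. Without it the log2 fold changes of SGK1 and HSP90AB1 were -0.40 and -0.77, and that of TSC22D3 was 0.96 in place of 1.496. Genes of heat shock and oxidative stress had 22 of 32 tested members higher (median 0.26, camera adjusted p = 0.364). The peroxiredoxin gene PRDX1 had a log2 fold change of 3.47 ± 1.51 (SE), with 71.3 CPM in Maltreated 3 against 1.34 and 10.7 in the other Maltreated libraries, and PRDX5 one of -1.01 ± 0.54. Without Maltreated 3 that of PRDX1 was 1.25. TXNRD1, a thioredoxin reductase gene, stood at 138 ± 56.8 CPM (SD, n = 4) against 220 ± 8.79 (SD, n = 3), above every Control library in 3 of 3 Maltreated libraries.

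Genes of chromatin and DNA methylation had 27 of 60 tested members higher and 33 lower (median log2 fold change -0.06, camera adjusted p = 0.830). The 3 members with the smallest p had lower means in Maltreated sperm. KDM6B, a histone demethylase gene, stood at 60.4 ± 64.6 CPM (SD, n = 4) against 8.60 ± 4.77 (SD, n = 3), and CHD3, a chromatin remodeller gene, at 86.0 ± 143 (SD, n = 4) against 19.1 ± 4.10 (SD, n = 3). Control 4, the Control library with the most RNA of leukocyte genes, held 152 CPM of KDM6B and 299 of CHD3, and without it the log2 fold change of CHD3 was 0.35 in place of -2.17 and that of KDM6B -1.80 in place of -2.80. HDAC5, a histone deacetylase gene, stood at 54.7 ± 53.3 (SD, n = 4) against 12.9 ± 4.64 (SD, n = 3). Runs of identical counts held 34.95% of the counts of HDAC5, and with each exon reduced to its count above the lower neighbour its log2 fold change was 0.27 in place of -2.09. In the same setting that of KDM6B was -0.98 and that of CHD3 -0.52.

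Genes of the small RNA pathway had 17 of 31 tested members higher (median log2 fold change 0.13, camera adjusted p = 0.498), with AGO4, an Argonaute gene, at 0.47 ± 0.35 (SE), TARBP2 at 1.72 ± 1.53 and TSNAX at -0.95 ± 0.89. Neuronal and synaptic genes had 26 of 41 tested members lower (median -0.23, camera adjusted p = 0.532). Beside DLG4, the glutamate receptor gene GRM5 had a log2 fold change of 2.55 ± 1.29 (SE), or 1.62 without Maltreated 2, and the scaffold gene SHANK1 one of -2.07 ± 1.12. Imprinted genes had 10 of 17 tested members higher. Their median log2 fold change was 0.11 and their mean -0.01, and camera gave an adjusted p of 0.830 in the upward direction. IGF2R stood at 7.56 ± 4.18 CPM (SD, n = 4) against 28.3 ± 35.97 (SD, n = 3), with 69.5 CPM in Maltreated 3, the library with the most RNA of leukocyte genes, and its log2 fold change without that library was 0.015 in place of 1.91. KCNQ1 stood at 10.7 ± 5.75 (SD, n = 4) against 3.19 ± 1.92 (SD, n = 3), below every Control library in 3 of 3 Maltreated libraries. UBE3A stood at 168 ± 117 (SD, n = 4) against 103 ± 6.10 (SD, n = 3). Control 4 held 340 CPM of it, and without that library its log2 fold change was -0.13 in place of -0.72.

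**Figure D4:**
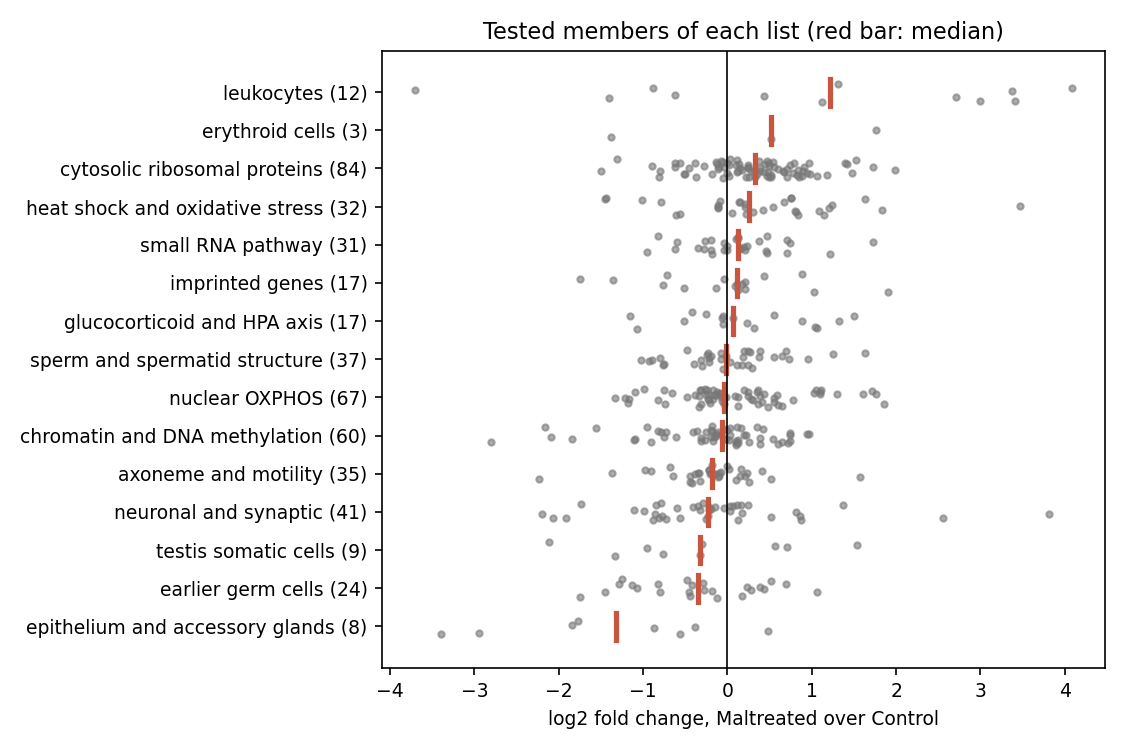
Log2 fold change of Maltreated over Control (horizontal axis) for each tested member of 15 gene lists (number of members in brackets); each grey point is a gene and the red bar the median of its list. The medians run from -1.32 for epithelium and accessory glands to 1.22 for leukocytes, and no single gene passed the edgeR test.

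By camera, 0 of 14 lists passed an adjusted p of 0.05. At an unadjusted p under 0.05 there were 2 lists, epithelium and ribosomal proteins, and with an estimated correlation or by fry there were none. With an estimated correlation 0 lists also passed without each library in turn. Within the lists 0 members passed over all genes tested, and 0 passed when adjusted over the list alone. No summed level of 15 lists passed the test between the groups (adjusted p = 0.943 for each list, exact permutation test, two-sided). The smallest possible p of this test, 0.0286 before adjustment, is too large for 1 list alone to pass. The lists of mitochondrially encoded genes and of structural noncoding RNA had 0 genes in the files. On simulated counts with the fitted spread, edgeR found 6 of 50 genes changed 4-fold, 22 of 50 changed 16-fold and 34 of 50 changed 64-fold. Changes of 4-fold were thus mostly not detectable in these 7 libraries.

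Antisense counts were compared in the same way, as RNA from the opposite strand of annotated genes. In edgeR 0 of 4382 genes passed (smallest adjusted p = 0.726), with 110 genes at an unadjusted p under 0.05. That number was 205 without Maltreated 1, 186 without Maltreated 2 and 173 without Maltreated 3. The DESeq2 Wald test called 16 genes, 7 higher and 9 lower in Maltreated sperm, among them SULT2B1, SPHK2, IL17RE, PFAS and HNF4A. Exons whose count equalled that of both neighbours held 22.6 to 49.2% of the antisense counts of a library, against 0.278 to 3.54% of the sense counts. On the forward files alone 0 of 7269 genes passed in edgeR, with 133 at an unadjusted p under 0.05 (221 without Maltreated 1). On the reverse files alone 0 of 7137 genes passed in edgeR, with 165 at an unadjusted p under 0.05. The forward and reverse counts mix sense and antisense reads according to the strand of each gene.

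Over all tested genes, Control 4 stood apart from the other libraries. Its median correlation of log2 CPM with the other 6, taken across genes, which are not independent replicates, was 0.672, and that of the others lay between 0.784 and 0.849. On the first principal component, with 37.7% of the variance, Control 4 stood at 203 and the other libraries between -52.3 and -15.6. The next component (22.4%) set Maltreated 2 apart at -151, and the one after it (16.8%) Control 3 at 129. None of the 3 components separated Maltreated from Control sperm.

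**Figure D5:**
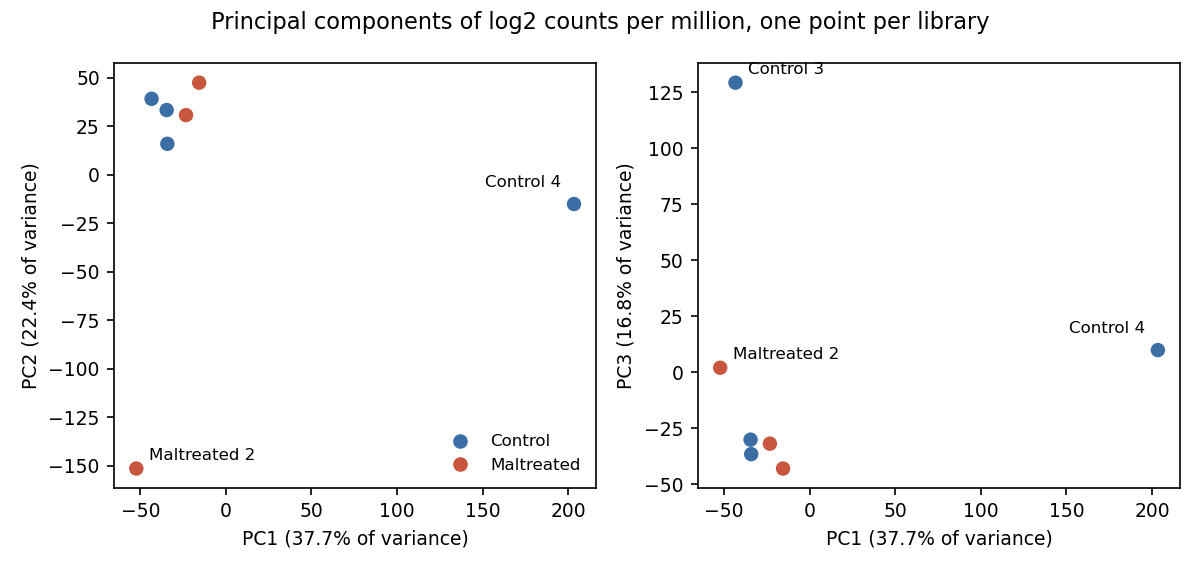
Principal components of log2 CPM of the tested genes, with the percent of variance on each axis; each point is 1 library, Control in blue and Maltreated in red. Control 4 lies alone at 203 on the first component, Maltreated 2 at -151 on the next and Control 3 at 129 on the one after.

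The composition of the libraries was compared over the 35 ways to split 7 libraries into 4 and 3, where the smallest possible p is 0.0286. Sense counts were 6673738 ± 2135377 (SD, n = 4) in Control and 15855526 ± 13066661 (SD, n = 3) in Maltreated libraries (exact permutation p = 0.0571, two-sided, adjusted p = 0.286). Antisense reads made up 9.56 ± 2.25% (SD, n = 4) and 8.10 ± 1.79% (SD, n = 3) of the counts, with an exact p of 0.4. The genes with a sense count numbered 13245 ± 597 (SD, n = 4) and 14549 ± 2765 (SD, n = 3), with an exact p of 0.429. The forward files held 49.7 ± 0.761% (SD, n = 4) and 49.6 ± 0.974% (SD, n = 3) of the counts, with an exact p of 0.971. The 10 most abundant genes of each library took 16.8 ± 2.10% (SD, n = 4) and 17.0 ± 1.95% (SD, n = 3) of its sense counts, with an exact p of 0.914. Adjusted over these 5 measures, the p ran from 0.286 to 0.971.

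Exon coverage was compared in the same way. The number of genes with at least 0.5 of their exon bases covered was 3750 ± 985 (SD, n = 4) in Control and 6305 ± 3868 (SD, n = 3) in Maltreated libraries, with an exact p of 0.314. With at least 0.9 covered it was 2629 ± 522 (SD, n = 4) and 4372 ± 2982 (SD, n = 3), also with an exact p of 0.314. The median covered percent of genes detected in every library was 25.9 ± 12.6 (SD, n = 4) against 54.1 ± 38.4 (SD, n = 3; exact p = 0.229). Its highest value, 93.1, belonged to Maltreated 1, the deepest library. That library also had the most genes at both thresholds, 10099 with at least 0.5 covered and 7555 with at least 0.9. The Control animals were 5.83 ± 0.0870 (SD, n = 4) and the Maltreated animals 5.72 ± 0.0557 years old (SD, n = 3), with an exact p of 0.114.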

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

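The tests of depth and of the splits of the libraries, and that of macrophage genes in Control 4 with Maltreated 3 set aside, were chosen only after the result was seen. In each of 98 measures of the 4 Control libraries, the gap between the highest or lowest library and the nearest other one was compared with the whole range of the group. In 10 measures the gap took an unusually large part of the range, against a nominal 4.9 by chance. The 10 cannot be read as an excess. PAQR6, IL17RC and LECT1 are among them because the other Control libraries had no count, and ANKRD36 and ANKRD36B can share reads. The 3 Maltreated libraries are too few for this comparison. Lists of macrophage and lymphocyte genes were written after the leukocyte levels and the genes highest in single libraries had been seen, but before any value of the macrophage genes listed was looked at. They share 0 genes with the other lists, and 39 macrophage genes reached 5 CPM in some library, 21 of them in some of the 5 libraries other than Control 4 and Maltreated 3. Genes of 1 cell type vary together, so no p is given for these lists.

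Leukocyte genes summed to 757 CPM in Control 4, against 13.4 to 71.5 in the other Control libraries, and to 1128 in Maltreated 3. Counts from reads that only span the exons are argued against, since with each exon reduced to its count above the lower neighbour the sums were 35.03 (Maltreated 3) and 19.48 (Control 4) times the median of the other 5 libraries. RNA of lymphocytes in Maltreated 3 found no backing in the summed level of all 24 listed lymphocyte genes. It was 24.6 CPM, within the 12.8 to 27.9 of the other 5 libraries. Of the 7 that reached 5 CPM in some library 1 was highest in Maltreated 3, but 4 were highest in Control 4, which leaves few. CD22 at 8.89 CPM and IL7R at 3.46 lay above the other 5 libraries, with at most 1.12 and 0.167. The rest of the 7 lay within them, so some lymphocyte RNA is not excluded. RNA of macrophages, which the density gradient should remove, is a candidate source in Maltreated 3, where 33 of 39 macrophage genes were highest, among them 19 of the 21 that also reached 5 CPM in some of the other 5 libraries, with CTSB at 687 CPM, PSAP at 467 and CTSD at 287. In Control 4 only 5 were highest. The outcome written down beforehand was a wrong one, since Maltreated 3 leaves Control 4 few genes to be highest in. With Maltreated 3 set aside 28 of 39 were highest in Control 4, but this library is often the highest. Random lists of genes with like mean expression gave 13.4 of 39 on average. Some lymphocyte genes were high in Control 4 too, above all LCK at 113 CPM. With Maltreated 3 set aside 4 of 7 were highest there, against 2.88 on average in random lists. The kind of leukocyte stays open, and a difference between the animals in leukocytes stays open as untested.

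The summed level of the macrophage list was 1214 CPM in Control 4, 3559 in Maltreated 3 and 125 to 234 in the other libraries. In Control 4 CTSB stood at 235 CPM, FTL at 116 and B2M at 115. Whether the genes of the list are specific to macrophages was not tested. CSF1R stood at 35.7 CPM in Maltreated 3 and 26.7 in Control 4, against 0.162 to 9.995 in the other libraries. TREM2 stood at 8.70 CPM in Maltreated 3 and 9.03 in Control 4, with no count in the others. SPI1 stood at 21.9 CPM in Maltreated 3, but at 0.940 in Control 4, within the 0.162 to 2.23 of the others. Of 4 neutrophil genes 0 were highest in Maltreated 3 and 2 in Control 4. Of the 7 lymphocyte genes that reached 5 CPM in some library 4 were highest in Control 4. The whole list of 24 lymphocyte genes summed to 164 CPM there, with LCK at 113, IL7R at 19.2, PAX5 at 15.6 and KLRD1 at 5.08.

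Over all tested genes Control 4 correlated least with the other libraries. Lower depth is argued against as the whole cause, since after thinning to 1 depth its median correlation with the others was 0.6683 and that of the other libraries at least 0.818. Counts from reads that only span the exons are argued against as well, with 0.6999 in Control 4 and at least 0.8419 in the others once each exon was reduced to its count above the lower neighbour. Few distinct RNA molecules behind the reads of Control 4 stay open: in exons of 300 to 1000 nt with 20 to 50 counts, the median covered percent was 28.29 in Control 4, 37.4 in Maltreated 2, 51.95 in Control 3 and 87.9 to 100 in the other libraries. No biological explanation was tested, as the labels give nothing by which Control 4 differs from the other Control animals but age.

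Runs of exons with identical counts, as over CA11, NTN5 and DBP, are consistent with reads counted on every exon that their alignment spans. At least 95.31% of such sense exons were covered over their full length in every library, against 29.4 to 52.3% of other exons of like count and length. Exons of 1000 nt or more with a single sense count were fully covered in 23.7 to 33.3% of cases, the longest being 12072 nt in Maltreated 3. Such counts do not show that every exon of a gene was transcribed, and no biological explanation of the runs was tested.

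The other measures are given as values. Control 1 had 9847743 sense counts, the most of its group, against 5316383 to 6002772 in the other Control libraries. Of the Control libraries, Control 4 had the lowest summed CPM of the genes of sperm and spermatid structure, 54135 against 63077 to 64855. Maltreated 2 and Maltreated 3 stood lower still, at 50336 and 52608. The log2 CPM of TSC22D3 was 2.10 in Control 4 and 0.28 to 0.56 in the other Control libraries. For ANKRD36 it was 13.75 in Control 4 against 14.03 to 14.07, and for ANKRD36B, which can share its reads, 13.05 against 13.34 to 13.37. CEP112 stood at 13.36 in Control 3 and 12.87 in the other Control libraries. Only 1 Control library had any count of PAQR6 (Control 3, log2 CPM 0.063), of IL17RC (Control 2, -1.43) and of LECT1 (Control 1, 1.67), where the others stood at -2.39, the value of a count of 0.

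The real split of the 7 libraries gave 0 calls for sense, antisense, forward and reverse counts and for gene lists. Any split gives at least as many, so the count of 35 of 35 splits was fixed beforehand and says nothing about chance. The highest other split gave 2 genes for sense counts, 1 each for antisense, forward and reverse counts, and 4 gene lists.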

How the results depend on the processing

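The settings with unique exons, exon counts above the lower neighbour, sense plus antisense counts, Control 4 and Maltreated 3 both left out, all of the antisense comparison, and the estimated correlation with the block, with exon counts above the lower neighbour or without each library were chosen only after the data were seen. Of 1593 results under an alternative, 1581 stayed on the side of the threshold of the reported value and 12 passed it where the reported value had not. No reported value had passed, and 1458 of the 1593 belong to single named genes. Staying on that side was thus close to fixed beforehand and does not show that a value is stable. In genes whose reported fold change lay within 1 SE of 0, 14 moved by more than 1 SE, 8 of them with a change of sign, and in other genes 30 changed sign. The cause was not tested in any of these. The count of genes stayed 0 under every setting run on the forward and reverse files. For sense counts the DESeq2 Wald test called 3 genes and age as a covariate called 1 (CD63, higher), and for antisense counts the DESeq2 Wald test called 16; the other settings called 0. The labels do not say whether the replicate numbers pair the animals. With group means removed, same-number libraries had correlations of 0.0749, 0.00993 and -0.0194, and other pairs -0.114 to 0.0932. These few values cannot settle the pairing. With the replicate block 0 genes passed and 1 list, leukocytes, passed upwards (adjusted p = 0.000196, limma). Only Control 4 carries its replicate number, so the block fits that library exactly. The group effect then rests on the other libraries, much as when Control 4 is left out. Leaving out 1 library gave 0 to 2 lists: leukocytes without Control 4 or without Maltreated 1, ribosomal proteins without Control 2, and axoneme and ribosomal proteins without Maltreated 2. Exon counts above the lower neighbour gave 1, ribosomal proteins. All these list calls rest on the preset correlation: with an estimated one 0 lists passed in each of these settings, and the adjusted p of leukocytes with the block was 0.895.

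Sign changes of single genes were first 73. After they were seen, the forward and reverse files were no longer read as alternatives for 1 gene, being its sense or antisense count, and no direction was read from a fold change within 1 SE of 0 (11 genes, 29 sign changes). Of 74 named genes, 61 had no other sign change. Leaving out 1 library moved 41 of the 74 by more than 1.5-fold and 37 by more than 1 SE. Exon counts above the lower neighbour moved 12 of the 60 genes still tested by more than 1.5-fold, each toward 0, and left 14 with too few counts. Among other settings, age moved 33 of the 74 by more than 1.5-fold, limma-voom 31, leaving out Control 4 and Maltreated 3 together 28, the replicate block 25, and added antisense counts 10. The log2 fold changes that changed sign were, by limma-voom, CRISP2 0.10, KRT8 0.31, UQCRFS1 0.029 and CHD3 0.49; with the replicate block, CRISP2 0.085, SYCP3 0.43, C1QB 0.0011 and CHD3 0.64; and with age, CRISP2 0.19, SYCP3 1.82, UQCRFS1 0.23, CHD3 0.84 and UBE3A 0.22. With exon counts above the lower neighbour HDAC5 stood at 0.27. With Control 4 and Maltreated 3 both left out they were CRISP2 0.17, SYCP3 0.35, PTPRC -0.42, CD68 -1.18, SGK1 -0.73, HSP90AB1 -0.12, CHD3 0.27 and IGF2R -0.029. Leaving out 1 library in turn, CRISP2 ran from -1.20 to 0.073, SYCP3 from -2.13 to 0.19, C1QB from -4.26 to 0.11 and CHD3 from -2.56 to 0.35, each highest without Control 4. PTPRC ran from -0.81 to 3.93, CD68 from -2.16 to 5.13, SGK1 from -0.40 to 1.72 and HSP90AB1 from -0.77 to 1.72, each lowest without Maltreated 3. Of 61 alternatives of whole-library measures 5 changed sign, none with a call; leaving out a library leaves too few splits for an exact p under 0.05. Leaving out mitochondrial and structural noncoding genes was not applicable, as the files hold none. Depth limits single genes near the floor, such as PDCD1LG2, IL17RC and USHBP1, which rest on 434 counts or fewer.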

Other observations

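The pairs and groups of neighbouring genes given here were chosen after their values were seen. EIF4A1 and CD68 lie next to each other on the plus strand of chromosome 17, at 7473485 to 7480480 and 7481120 to 7483596, and both were highest in Maltreated 3, with 78.4 and 362 CPM (scaled with TMM factors). DNAH2, KDM6B and CHD3 lie between 7628555 and 7833580 on the same strand. In Control 4 they had 350, 152 and 299 CPM, and in the Maltreated libraries 118 to 140, 3.18 to 12.1 and 14.4 to 21.5. Control 2 had 369 CPM of DNAH2, 59.3 of KDM6B and 26.8 of CHD3. Control 1 and Control 3 had 105 and 115 CPM of DNAH2 and 5.33 and 12.5 of CHD3, below the Maltreated libraries, and 8.32 and 22.2 of KDM6B. Of the counts of these genes, 6.03, 33.2 and 27.7% lay in runs of exons with identical counts.

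The prostate genes TGM4 and MSMB set Control 2 apart from Maltreated sperm. TGM4 had 247 CPM in Control 2, 1.86 to 16.5 in the other Control libraries and 1.24 to 19.5 in the Maltreated libraries. MSMB had 25.2 CPM in Control 2, 20.8 in Control 3 and at most 2.48 in the other libraries.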
